A study of Drosophila melanogaster with 7 samples.

How the data were processed

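The series holds 7 Affymetrix fly arrays of salivary gland RNA, 1 array per sample. Per the labels, animals were reared at 25 °C, heat shocked for 30 min at 37 °C and dissected 14 h after puparium formation. RNA was extracted with TRIzol and RNeasy and labelled by a one-cycle protocol with biotin. Line X1 with 2 copies of a heat-shock GAL4 transgene had 3 arrays, which the series text calls biological replicates. Line 89 had 1 array from animals with 2 copies and 1 array from animals with 1 copy. The control strain w1118, which carries no GAL4, had 2 arrays, also called biological replicates. The 5 GAL4 arrays were heat shocked 9 h after puparium formation and the w1118 arrays at 9.5 h, so 5 h and 4.5 h passed before dissection.

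The deposited values are dChip expression values in units of intensity on a linear scale, and the authors normalised every array to one baseline array with a median intensity of 145 (series text and the values themselves). The dChip version, its expression model and its handling of low values were not given in the sources used here. The authors tested X1 against w1118 in GeneSpring at a false discovery rate of 0.05 (series text). The table used here held 18952 probe sets in 7 columns, with 0 columns from samples outside the series. Of these, 183 were Affymetrix control probe sets and were left out of the tests, which left 18769 fly probe sets. The table pairing probe sets with genes gave 1 symbol for 13647 of them, several for 402 and none for 4720. Of the probe sets with 1 symbol, 13544 matched the reference gene table of the Release 6 assembly by Entrez gene, and 0 symbols changed. These stood for 11982 genes, of which 1094 had more than 1 probe set. Among the latter, 16 had called probe sets in both directions in X1. The reference table was used for names and for which genes neighbour each other.

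Values under 16 were raised to 16 and converted to log2. Folds were taken from the difference of group means on this scale, and a fold is given as "at least" where every array of the dimmer group lay at or under 16. X1 and w1118 were compared in limma 3.58.1 (lmFit and eBayes, two-sided) under R 4.3.3, on the 3 X1 and 2 w1118 arrays with no covariates. Line 89 against w1118 and X1 against line 89 came from one limma fit of the 7 arrays in 3 groups, with both line 89 arrays as 1 group, so that the copy number difference counted as spread. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 over the 18769 fly probe sets. No array-wide depth exists for these data, and the number of arrays limits the precision. The errors given are the SD between arrays for intensities and the standard error from limma for log2 changes.

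Named genes followed a fixed rule. For X1 against w1118 they were the 10 largest rises and 10 largest falls among called probe sets with 1 symbol, a brighter group mean at or above the median of all probe set means (41.3) and no overlap between the arrays of both groups. The other 2 contrasts gave 5 in each direction. Each gene list gave up to 3 called members in each direction, by adjusted p. The white gene and every Hsp70 probe set were to be reported in any case. Genes chosen otherwise are named as such.

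The 21 gene lists were heat shock and chaperones, ecdysone response and prepupal regulators, cell death, autophagy, salivary gland glue and late prepupal secretion, innate immunity, detoxification, galactose pathway, transcription coactivators, cytosolic ribosomal proteins, proteasome, oxidative phosphorylation, glycolysis, circadian clock, cell cycle, and markers of fat body, hemocytes, muscle, midgut, neurons and cuticle. Each gene entered with its brightest probe set over the 5 arrays. A list member counted as measured only if a probe set with that 1 symbol was found, and the others are not in the counts. The largest such gaps were 27 immune members and 14 heat shock members. Lists were tested with camera (limma) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation. The rotation test fry (limma) asks whether the genes of a list move on balance one way, and its mixed form whether they change in either direction. Neither form of fry compares a list with other genes.

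Agreement between X1 and line 89 was set against 50 simulated pairs of unchanged line 89 arrays that shared the w1118 arrays. The simulated X1 arrays kept their changes for the share of calls and had none for the covariance and r. The copy number comparison of line 89 had 1 array on each side and no test, and its medians were set against 10000 random lists matched on mean expression in 20 bins. Groups, contrasts, tests, lists, the naming rule and most alternatives were fixed before the data were examined. Alternatives covered other normalisations, floors of 1 and 64, a filter on dim probe sets, other variance models, a replicate block, other thresholds and groupings, and leaving out each array. Scaling to the hybridization controls and a filter at a brighter group mean of 100 were added later. The planned test for GAL4 sites within 1000 bases upstream of transcript starts was not run, because no genome sequence was used here.

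The procedure was tested on simulated data with known changes on brighter probe sets. In the X1 design 11.9% of 2-fold, 37.3% of 4-fold and 57.6% of 8-fold changes were called, and 0 of 71 calls fell on unchanged probe sets. Only 67, 67 and 66 changes of these sizes were planted among 18769 probe sets, with errors independent between probe sets. In the real comparison 18.1% were called, which makes the adjustment less strict. The recovered shares therefore do not give the sensitivity of the real comparison. Unchanged probe sets made up 8.57% of the simulated calls for line 89 against w1118 and 6.56% for X1 against line 89. A planted list of 40 genes shifted by 1 on the log2 scale was called, with 0 of 20 other lists. Planted neighbouring pairs were recovered, with 66 pairs against at most 35 in shuffles. Figures and file handling used Python 3.11.15, matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6.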

Results

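Gene expression was measured on Affymetrix arrays in salivary glands of fly prepupae, 14 h after puparium formation. GAL4 is a yeast transcription activator that flies lack, and it is widely used in them to switch on transgenes. Here it was expressed from a heat-shock transgene. Line X1 with 2 copies had 3 arrays, line 89 had 1 array with 2 copies and 1 with a single copy, and the strain w1118 without GAL4 had 2. The w1118 animals were heat shocked at 9.5 h and the GAL4 animals at 9 h. An effect of this time or of strain background therefore cannot be told apart from that of GAL4 in any comparison with w1118. The X1 arrays also had less 5' signal in the bacterial control RNAs than the w1118 arrays, as given further below. Median intensity was 42.3 and 42.5 in the w1118 arrays, 33.7, 37.2 and 38.0 in X1, 44.9 in line 89 with 2 copies and 40.8 with 1 copy. Between 18.8% and 30.0% of the fly probe sets lay under an intensity of 16, the highest share in X1 replicate 1. Across probe sets, which are not independent replicates, log2 values correlated at r = 0.978 between the w1118 arrays. The X1 arrays correlated at r = 0.956 to 0.985 among themselves and at r = 0.847 to 0.878 with w1118.

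The first comparison asked which genes of the gland respond to GAL4 itself, and set X1 against w1118. With the floor of 16 the largest rise was in CG9733, from 4.39 ± 2.59 (SD, n = 2) in w1118 to 8717 ± 1478 (SD, n = 3) in X1, at least 539-fold. CG9449 rose 380-fold, from 26.4 ± 2.60 to 10010 ± 359. Expression of upd1, which encodes a ligand of the JAK/STAT pathway, rose from 12.2 ± 10.7 to 5610 ± 1266, or 310-fold with the floor of 16, which 1 of the w1118 arrays lay under. At the other end Cyp4e2, a cytochrome P450 gene, was 131-fold lower in X1, at 37.6 ± 5.22 against 4969 ± 1199 in w1118. Idgf3, which encodes a secreted imaginal disc growth factor, was 86.6-fold lower with the floor of 16, which 1 of the X1 arrays lay under, at 17.2 ± 5.50 against 1608 ± 476.

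On the log2 scale CG9733 changed by 9.08 ± 0.17 (SE; adjusted p = 0.000661), CG9449 by 8.57 ± 0.08 (adjusted p = 0.000427) and upd1 by 8.28 ± 0.25 (adjusted p = 0.00132). The next largest rises were CG6023 (8.09), scpr-C (7.97, at least 250-fold), CG14949 (7.93), the noncoding RNA lncRNA:CR31781 (7.67), hoe2 (7.61), the muscle troponin C gene TpnC73F (7.47, at least 177-fold) and CG9451 (7.42, at least 172-fold). Cyp4e2 changed by -7.03 ± 0.22 (adjusted p = 0.00133). It was followed by CG33127 (-6.50), Idgf3 (-6.44), CG3277 (-5.83), CG16890 (-5.52), the fat body protein gene Fbp2 (-5.51), ldd (-5.44), CG4757 (-5.29), CG14292 (-5.20, at least 36.7-fold lower) and CG9021 (-5.17). For lncRNA:CR31781, hoe2, Idgf3 and CG16890, too, 1 array of the dimmer group lay under the floor. Across the alternatives (here and below without the replicate block) the change ranged from 6.43 to 9.17 for upd1 and 5.71 to 7.90 for lncRNA:CR31781. It ranged from 6.20 to 8.20 for hoe2, -6.74 to -4.62 for Idgf3 and -5.75 to -4.31 for CG16890. The lowest change was 7.08 for CG9733, 7.29 for CG9449 and 7.46 for CG14949, so the first rank of CG9733 is not fixed. With all 5 GAL4 arrays as 1 group the calls of scpr-C, CG9451 and each of the 10 largest falls except CG33127 ended, and the line 89 values of CG4757 (3687 and 1702) were near its w1118 mean of 2303.

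**Figure D1:**
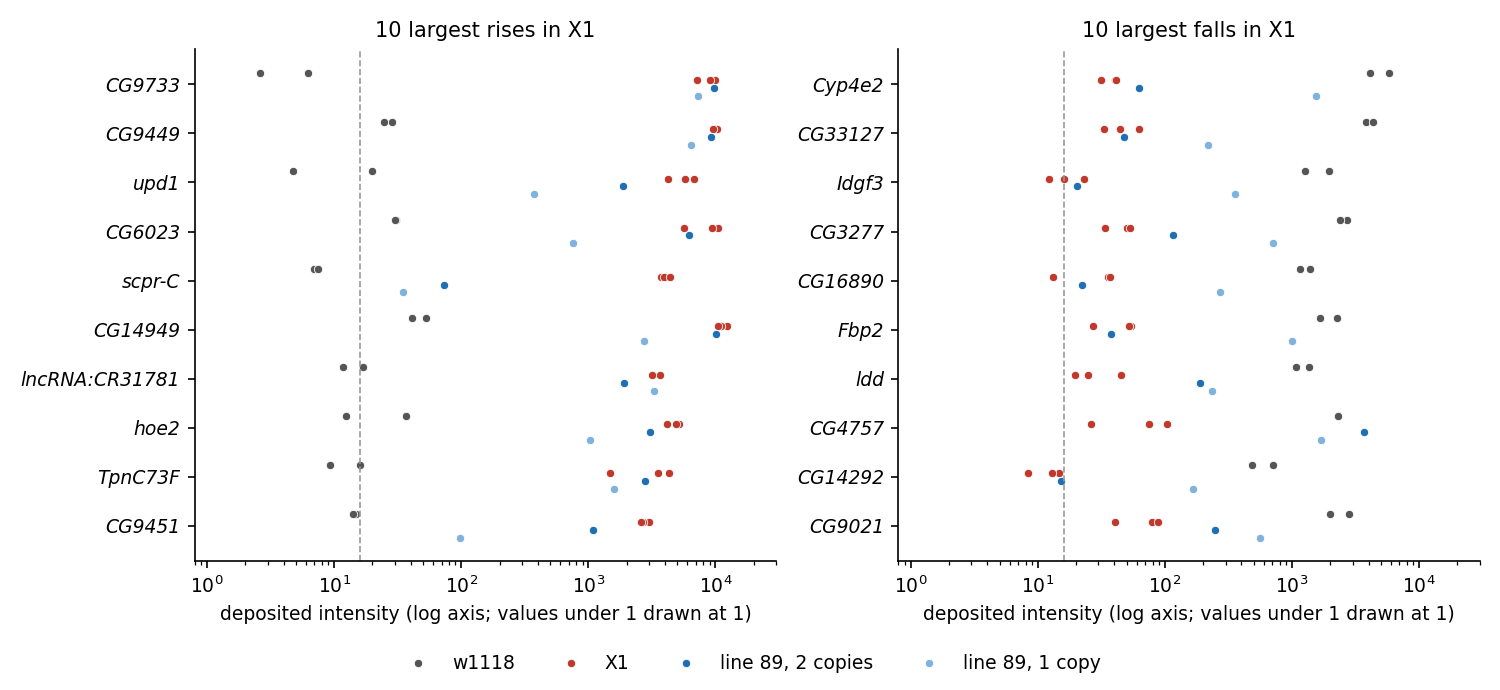
Intensity (log axis) of the 10 genes with the largest rise and the 10 with the largest fall in X1, with 1 point per array for w1118, X1 and line 89; the dashed line marks the floor of 16. CG9733 lay at 4.39 on average in w1118 and at 8717 in X1.

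In all, 3404 of 18769 probe sets (18.1%) were called in X1 against w1118, 1407 higher and 1997 lower. Large changes were mostly rises: 317 probe sets rose and 117 fell at least 8-fold, and 21 rose and 1 fell at least 100-fold. Among probe sets with a brighter group mean of at least 1000, 591 rose and 165 fell, whereas 145 rose and 812 fell where that mean was under 64. Falls no longer outnumbered rises with a floor of 1 (1211 rises, 1201 falls), a floor of 64 (720, 674), all 5 GAL4 arrays as 1 group (624, 606), adjusted p under 0.01 (602, 579), a brighter group mean of at least 100 (1485, 1435) or hybridization scaling (1964, 612), which moved the median of all changes by 0.295 from -0.09, and no moderation of the variance gave 1822 calls. With the replicate number as a block limma called 0 probe sets (4491 at an unadjusted p under 0.05), without X1 replicate 2 or 3 the count was 1619 or 1663, and without w1118 replicate 1 or 2 there were 692 or 730 rises and 1623 or 1653 falls.

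Genes of the stress and hormone lists moved in part, and of 104 named values of X1 against w1118, most of them from the lists, 66 lost their call with all 5 GAL4 arrays as 1 group. Over all 11982 genes in the list tests 2510 were called, 1132 higher and 1378 lower, and the counts of each list are to be read beside that share. Of 19 measured genes for heat shock proteins and chaperones, 4 rose, 0 fell and 15 were not called, with the same 4 and 0 when adjusted over the list alone. The 14 members not measured include Hsp83, Hsp22, Hsp23 and the Hsp70 genes. The risers were Hsc70-4 (4261 to 8111, log2 change 0.93), the Hsp90 partners Cdc37 (614 to 1291, 1.07) and Stip1 (2.10), and the DnaJ-like Droj2 (1.19), of which Hsc70-4, Cdc37 and Droj2 held their calls in 11, 11 and 10 of 16 alternatives. Of the 5 Hsp70 probe sets, each of which lists several genes, 4 were not called. The w1118 replicates differed widely in 3 of these, at 462 and 2822, 401 and 2080, and 1428 and 5581, and replicate 2 was the higher each time. The X1 mean of the first was 3245 ± 1545 (adjusted p = 0.408). The other Hsp70 probe set also lists CG31343 and fell at least 1.75-fold, from 28.1 to 3.73 (adjusted p = 0.0183), with every X1 array under 16. No probe set of the annotation used here named white. Among 31 genes of the ecdysone response, 4 rose and 6 fell (4 and 2 with hybridization scaling), or 4 and 8 adjusted over the list alone. Eip74EF and Eip75B of this list were not measured. ImpL2, a secreted insulin antagonist, rose from 266 to 8420 (4.99 ± 0.15, adjusted p = 0.00132). The nuclear receptor gene Hr78 rose by 1.41, while the ecdysone receptor gene EcR fell from 738 to 300 (-1.30) in X1, with 719 and 914 in line 89 with 2 copies and 1 copy, and the nuclear receptor gene Eip78C fell by 2.90 on the log2 scale.

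Death, autophagy and secretion genes went both ways. In the cell death list 3 of 20 genes rose and 2 fell (3 and 4 after quantile normalization), or 6 and 4 adjusted over the list alone. Its members rpr, hid, Drice, Diap1 and Decay were not measured. Fadd, an adaptor of caspase signalling, rose from 60.7 to 688 (3.49), and Debcl of the Bcl-2 family rose from 297 to 3502 (3.53). Dark, which encodes the apoptosome scaffold, fell from 5277 to 1989 (-1.43), and the Bcl-2 family gene Buffy fell by 1.90 on the log2 scale, but these 2 calls held in only 9 and 8 of 16 alternatives and ended with hybridization scaling. Of 24 autophagy genes 2 rose and 2 fell, the same adjusted over the list alone. Atg14 rose by 1.78 and the autophagy receptor gene ref(2)P rose from 2820 to 10070 (1.84; 4614 and 2307 in line 89 with 2 copies and 1 copy), while Atg3 (-1.18) and Atg12 (-1.43) fell, with calls held in 11 and 9 of 16 alternatives. Of 24 glue and late secretion genes 3 rose and 2 fell (3 and 4 after quantile normalization), again the same adjusted over the list alone. The rises of Eig71Eg (0.42) and Eig71Eh (0.44) were small. Eig71Eh lay at 8223 and 4528 in line 89 with 2 copies and 1 copy, under its w1118 mean of 9211. The calls of the glue genes Sgs7 (-1.12) and Sgs3 (1.15) and the gland transcription factor gene sage (-1.13) held in 11, 7 and 6 of 16 alternatives.

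Immune genes were called in equal numbers, 9 higher and 9 lower of 44 (10 and 4 with hybridization scaling), or 11 and 13 adjusted over the list alone. The 27 immune members not measured include AttA, CecA1, DptA and PGRP-LC. PGRP-LB, which encodes an enzyme that degrades peptidoglycan, rose from 69.4 to 5803 (6.39). The Toll ligand gene spz rose from 210 to 5819 (4.82) and the NF-κB gene dl from 57.7 to 921 (4.01), while Tep3 fell by 1.83 and Drsl5 by 1.02 on the log2 scale. With a floor of 64 both calls ended (-0.05 for Tep3), and that of Drsl5 held in 8 of 16 alternatives. Detoxification genes had 3 rises and 14 falls of 64, with 47 not called, the same adjusted over the list alone. This list was dim, with a median w1118 intensity of 45.6, in the range where falls outnumbered rises among all probe sets. GstD9, a glutathione S-transferase gene, fell from 518 to 56.3 (-3.21), and Cyp4e2 of the largest falls is in this list. The P450 gene Cyp6a20 rose from 35.1 to 2355 (6.05) and Trxr1, for thioredoxin reductase, rose by 2.48.

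Among 14 glycolysis and gluconeogenesis genes 6 rose and 2 fell, or 7 and 4 adjusted over the list alone. Pgk rose from 564 to 2712 (2.27 ± 0.06, adjusted p = 0.00109), Gapdh1 rose by 1.39 and the gluconeogenic gene Pepck1 from 2433 to 12390 (2.36). The gluconeogenic gene fbp (-1.34) fell, with its call held in 10 of 16 alternatives, and that of the glycolytic gene Pfk (-0.86) held in only 4 of 16 (-1.02 to -0.25). Of 75 genes of oxidative phosphorylation 3 rose and 12 fell (3 and 2 with hybridization scaling), the same adjusted over the list alone. COX7A rose by 1.25 and ATPsyngamma by 1.18 (call held in 11 of 16 alternatives), and ND-13B fell by 1.35 on the log2 scale. Both called members of the 10 clock genes were the repressors tim, from 85.3 to 7779 (6.51), and per, from 10.5 to 751 (5.54, at least 46.4-fold). Adjusted over the list alone, the clock list had 2 rises and 1 fall.

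The galactose pathway, which GAL4 controls in yeast, had 0 rises and 3 falls among 9 fly genes, the same adjusted over the list alone. CG10467 fell from 498 to 163 (-1.61; 110 and 502 in line 89 with 2 copies and 1 copy), and Galt changed by -0.60, or 0.01 with hybridization scaling, with its call held in 6 of 16 alternatives. CG32445 fell from 27.2 to 8.63, at least 1.70-fold, but every X1 array lay under 16 and the call ended with a floor of 1 or 64. Among 49 genes of transcription coactivators 5 rose and 10 fell, or 6 and 13 adjusted over the list alone, and 10 rose and 4 fell with hybridization scaling. The TFIID genes Taf1 (2.02) and Taf10b (1.70) and the Brahma complex gene mor (1.53) rose, and MED27 (-1.77) and Taf13 (-1.43) fell. Cytosolic ribosomal protein genes had 1 rise and 1 fall of 41, with 0 of either adjusted over the list alone. RpS10a changed by -1.07, with its call held in 7 of 16 alternatives, and RpL24-like by 0.32, or -0.02 after quantile normalization, held in 2 of 16. Proteasome genes had 2 rises and 1 fall of 40 (1 and 6 after quantile normalization), or 1 and 0 adjusted over the list alone, led by the beta subunit gene Prosbeta2R2 (5.23, at least 37.4-fold). Rpn1 rose by only 0.36 and turned after quantile normalization, and Rpn12 changed by -0.80. Of 21 cell cycle genes Mcm2 (1.53) rose and Orc2 (-1.51) and mad2 (-1.09) fell, 1 and 2 genes (2 and 1 with hybridization scaling), the same adjusted over the list alone. All 3 calls ended with a floor of 64 (0 for Orc2), and that of mad2 held in 7 of 15 alternatives.

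Among markers of other tissues, 16 muscle genes had 2 rises and 3 falls (2 and 0 with hybridization scaling), the same adjusted over the list alone: the brighter TpnC73F probe set rose from 165 to 12760 (6.28), sls rose by 1.66 (call held in 10 of 16 alternatives), and Mlc1 (-1.27), Act87E (-0.85) and Act79B (-0.70) fell, with calls held in only 7, 4 and 6 of 16 alternatives. Of 15 fat body genes 1 rose, Lsd-1 for a lipid droplet protein (3.80, call held in 11 of 16 alternatives), and 2 fell, Fbp2 (-5.51) and Yp1 (35.0 to 9.30, at least 2.18-fold). Hemocyte markers had 0 rises and 2 falls of 17, Ppn (-1.20) and NimC1 (-1.17). Midgut markers had 1 rise, thetaTry (0.86), and 3 falls of 27 (1 and 1 with hybridization scaling), among them LysP (-2.42), and the calls of NimC1 and thetaTry held in 6 of 15 alternatives each. Neuron markers had 0 rises and 1 fall of 17, ChAT (79.3 to 12.3, at least 4.93-fold), whose call ended with a floor of 64 (-0.30). These counts of fat body, hemocyte, midgut and neuron genes were the same adjusted over the list alone. Of 112 cuticle genes 6 rose and 10 fell (8 and 3 with hybridization scaling), or 4 and 7 adjusted over the list alone, with Pcp (3.38) and Cpr49Ac (2.91) higher and Cpr31A (-2.39) lower.

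**Figure D2:**
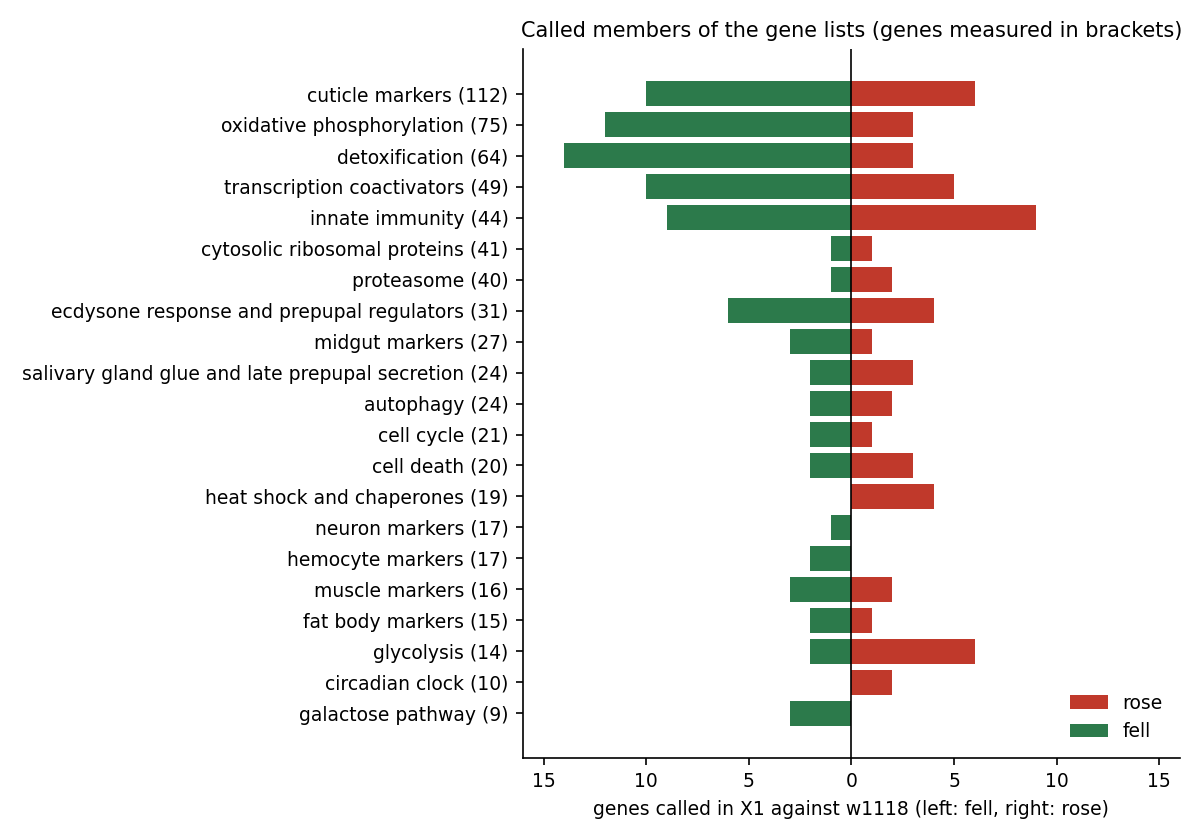
Number of genes called lower (left) and higher (right) in X1 against w1118 in each of the 21 gene lists. Detoxification had 3 rises and 14 falls, and glycolysis 6 rises and 2 falls. Over all 11982 genes 1132 were called higher and 1378 lower.

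As sets compared with the other genes, 0 of the 21 lists were called by camera, with 4 at an unadjusted p under 0.05. The smallest adjusted p was 0.108 for heat shock and chaperones (median log2 change 0.53), followed by detoxification (-0.47) and glycolysis (0.55), both at adjusted p = 0.114. With an estimated correlation the smallest adjusted p was 0.873. By fry, 9 lists moved on balance one way and 21 changed in either direction. The lists that fry called higher were glycolysis, innate immunity, clock and muscle, and those called lower were detoxification, galactose pathway, cell cycle, fat body and midgut. Median and mean had opposite signs for cell death (-0.19 and 0.19), innate immunity (-0.29 and 0.18), clock (-0.42 and 0.80) and muscle markers (-0.12 and 0.30), and camera's direction followed the mean in these 4. For the ecdysone list the median was -0.57 and fry's direction, not called, was up.

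Line 89 was set against w1118 to ask whether another GAL4 line responded alike. CG9733 again showed the largest rise, to 9725 with 2 copies and 7332 with 1 copy, at least 528-fold (9.04 ± 0.22, adjusted p = 0.000305). CG9449 rose 292-fold and CG15861 206-fold, and lncRNA:CR31781 changed by 7.26, or 5.29 to 7.64 across the alternatives, with a w1118 array under the floor. CG3770 rose 149-fold, from 71.0 to 10810 and 10280 (7.22 ± 0.09, adjusted p = 7.08e-05). The largest falls were CG33127 (-5.32, adjusted p = 0.0323) and Npc2e, of the Npc2 family of lipid-binding proteins, from 989 to 23.5 and 48.1 (-4.84 ± 0.40, adjusted p = 0.00783). They were followed by CG1941 (-4.16), the germline gene otu (-3.98, adjusted p = 0.0470) and CG8646 (-3.96). The calls of CG33127, otu and CG8646 held in 9, 8 and 6 of 15 alternatives, and CG8646 lost its call with a floor of 1 or 64.

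Altogether 822 probe sets were called in line 89, 513 higher and 309 lower, and 154 of the rises and 18 of the falls were at least 8-fold. Among the lists, 5 immune genes rose and 0 fell, 3 glycolysis genes rose and 1 fell, and 3 cuticle genes rose and 1 fell. The ecdysone and detoxification lists each had 2 rises and 2 falls, and coactivators 2 rises and 1 fall. Muscle markers had 2 rises, and the cell death, clock and oxidative phosphorylation lists 1 rise each, with 0 falls. Neuron markers had 1 fall, and the other lists had 0 calls. Scaling to the hybridization controls gave 1439 rises and 96 falls, a floor of 1 gave 345 and 64, a floor of 64 gave 489 calls, no moderation of the variance gave 438, and a replicate block gave 0 in limma with 2317 at an unadjusted p under 0.05. The excess of rises turned without w1118 replicate 1 (178 rises, 300 falls) or replicate 2 (193 rises, 317 falls), and the count was 289 or 254 without X1 replicate 2 or 3, and 1804 without the array of line 89 with 1 copy.

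Of the genes called in both lines, most had the same direction. Of the line 89 rises 423 (82.5%) were also X1 rises, against 38.5 for independent calls, and of the line 89 falls 299 (96.8%) were also X1 falls, against 32.9. Calls in opposite directions numbered 8. Of the 3404 X1 calls, 2529 (74.3%) lay on the X1 side of the w1118 mean in both line 89 arrays, compared with 35.3% on average and at most 36.4% for simulated unchanged arrays that shared the controls. Among rises of at least 8-fold the share was 95.0% (301 of 317), and among falls of that size 91.5% (107 of 117). The covariance of the X1 and line 89 log2 changes over probe sets was 0.697, against 0.054 in the simulation, a difference of 0.643. Their Pearson r was 0.786, against 0.548 on average and at most 0.572 in the simulation. For the covariance and r the simulated X1 arrays were unchanged as well. These simulated values thus show what shared controls give with no change in either line. With 2 w1118 arrays the controls were not split between the comparisons, so the simulation alone accounts for the shared controls. Its errors were independent between probe sets, so a shift common to all GAL4 arrays is not covered.

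**Figure D3:**
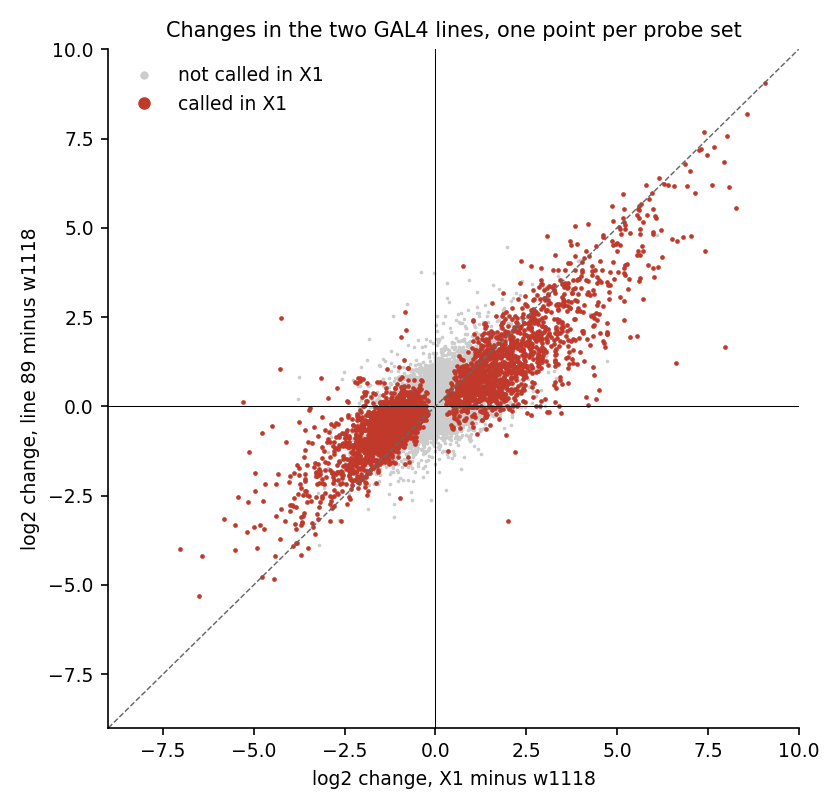
Log2 change from w1118 in line 89 (both arrays averaged) against that in X1, 1 point per probe set, with the dashed line marking equal change. Of the X1 calls, 74.3% lay on the X1 side of w1118 in both line 89 arrays.

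A direct comparison of X1 with line 89 asked which genes differed between the lines. All X1 arrays had 2 copies and 1 of the 2 line 89 arrays had 1 copy, so copy number and line are partly mixed in it. The X1 arrays also had less 5' signal in the bacterial control RNAs than the line 89 arrays, as given further below. The gene scpr-C was 78.7-fold higher in X1, at 4010 ± 367 (SD, n = 3) against 73.8 with 2 copies and 35.0 with 1 copy of line 89 (6.30 ± 0.33, adjusted p = 0.00913). The pair-rule homeobox gene eve reached 281 ± 8.55 in X1 against 23.2 and 2.12 (3.86 ± 0.17, adjusted p = 0.00913), or 2.13 to 5.32 across the alternatives, with the call lost with a floor of 1 or without X1 replicate 2 or 3. Also higher in X1 were CG14109 (5.19), the bHLH gene HLH3B (4.17) and the teneurin gene Ten-a (3.48). Lower in X1 was CecB, which encodes an antimicrobial cecropin, at 224 ± 113 against 6259 and 10550 (-5.34 ± 0.59, adjusted p = 0.0340). CG4783 was at least 106-fold lower (-6.73, adjusted p = 0.0387), and CG4757 (-5.41), mthl8 (-4.16) and the potassium channel gene Irk1 (-4.04) were lower as well. HLH3B, with a line 89 array under the floor, ranged from 2.62 to 4.62 across the alternatives, and mthl8, at 12.3 on average in X1, from -4.93 to -2.28 with its call lost with a floor of 1. Calls held in 8 of 15 alternatives for CecB, CG14109, CG4783, CG4757 and Irk1, in 9 for HLH3B and Ten-a and in 10 for mthl8.

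In this contrast 371 probe sets were called, 137 higher and 234 lower in X1, of which 13 and 16 differed at least 8-fold. Quantile normalization gave 146 higher and 125 lower, and a shift of each array to one median gave 180 and 109. The count was 62 or 113 with a floor of 1 or 64, 67 with no moderation of the variance and 0 in limma with a replicate block (2455 at an unadjusted p under 0.05), and it was 0 without X1 replicate 2 or 3, 186 (105 higher, 81 lower) without X1 replicate 1, 70 without either w1118 array, and 1138 or 985 without the line 89 array with 2 copies or 1 copy.

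The last comparison asked whether the response grew with the number of transgene copies in line 89. Values of upd1 were 12.2 in w1118, 376 with 1 copy and 1872 with 2 copies, and those of tim were 85.3, 1131 and 4249. For per they were 10.5, 29.6 and 135, and for CG9451 14.4, 97.3 and 1079. Cyp4e2 went from 4969 in w1118 to 1537 with 1 copy and 62.1 with 2, and Fbp2 from 1957 to 996 and 37.7. CG9733 and CG3770 differed less between 1 copy (7332 and 10280) and 2 copies (9725 and 10810). The order was the other way for lncRNA:CR31781, with 14.2 in w1118, 3265 with 1 copy and 1919 with 2, and for Hr78, with 2747, 9989 and 6550.

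Over the X1 rises the median log2 change from w1118 was 0.95 with 1 copy and 1.37 with 2 copies, compared with 1.84 in X1. Over the X1 falls it was -0.51, -0.70 and -1.21. The median difference of 2 copies minus 1 copy was 0.38 for the rises, with 950 of 1407 (67.5%) higher with 2 copies than with 1, and random matched lists gave -0.135 to 0.025. For the falls it was -0.15, with 1136 of 1997 (56.9%) lower with 2 copies, against -0.011 to 0.075. It was 0.79 for rises and -1.16 for falls of at least 8-fold, with 250 of 317 higher and 94 of 117 lower with 2 copies. Ties at the floor counted as neither. Each copy number had 1 array, so no test was made. A strain background that differs with the number of copies cannot be told apart from an effect of GAL4 here either. The arrays also differed in signs of RNA quality and heat shock. With 2 copies and 1 copy the 18S rRNA control (3' probe set) was 574 and 147 and an Hsp70 probe set 10180 and 4230. The log2 ratio of 5' to 3' signal was -1.09 and -0.53 for Act5C, -0.54 and -0.28 for GAPDH and -1.44 and -0.80 for eIF-4a. The median was 0.124 for rises with hybridization scaling, and for falls it ranged from -0.538 with that scaling to 0 without either w1118 array.

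**Figure D4:**
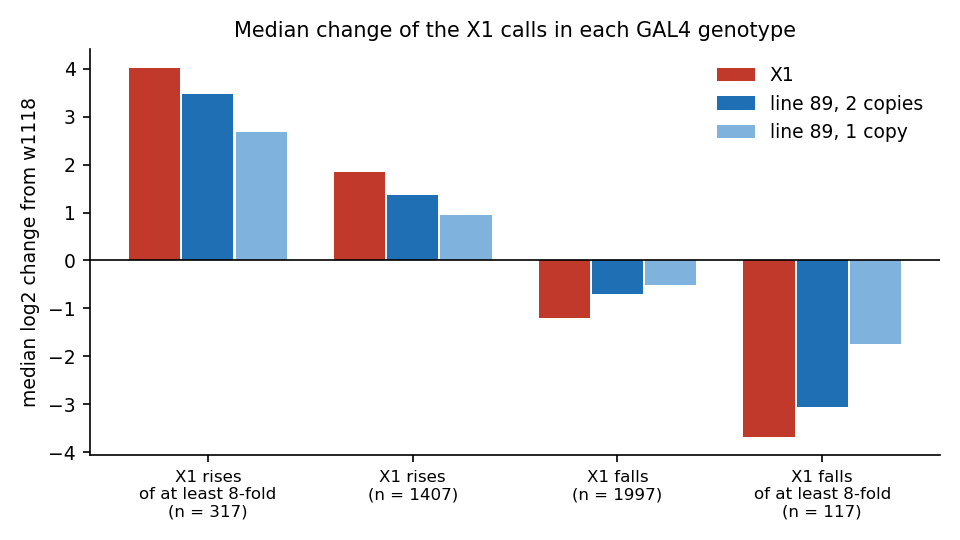
Median change from w1118 (log2, bars) in X1 and in line 89 with 2 copies or 1 copy, for the rises and falls called in X1 and those of at least 8-fold. For line 89 with 1 copy, 2 copies and X1, median changes of the rises were 0.95, 1.37 and 1.84. The probe sets were called on the X1 values, which favours large changes in X1.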

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

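The difference between the GAL4 lines was tested directly, in a contrast fixed in advance, and 371 probe sets were called between X1 and line 89. Line and copy number are partly mixed in this contrast, because 1 line 89 array had 1 copy. Among the genes singled out by the naming rule, scpr-C was higher in X1 by 6.30 on the log2 scale, with 4010 in X1, 7.13 in w1118, and 73.8 (2 copies) and 35.0 (1 copy) in line 89. CG14109 was higher by 5.19, with 6589 in X1, 1661 in w1118, and 88.8 and 367 in line 89. HLH3B was higher by 4.17 (401 in X1, 22.2 in w1118, 30.1 and 12.9 in line 89) and eve by 3.86 (281 in X1, 8.03 in w1118, 23.2 and 2.12 in line 89). Ten-a was higher by 3.48, with 263 in X1, 55.9 in w1118, and 18.4 and 28.6 in line 89.

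CG4783 had the largest fall of this contrast at -6.73, a bound set by the floor of 16, with 6.10 in X1, 317 in w1118, and 4295 and 669 in line 89. CG4757 differed by -5.41 (68.3 in X1, 2303 in w1118, 3687 and 1702 in line 89). CecB differed by -5.34 (224 in X1, 4034 in w1118, 6259 and 10550 in line 89). The difference was -4.16 for mthl8 (12.3 in X1, 22.6 in w1118, 337 and 289 in line 89) and -4.04 for Irk1 (183 in X1, 5015 in w1118, 1892 and 4640 in line 89). These calls rest on few arrays: without X1 replicate 2 or 3 the contrast had 0 calls, without replicate 1 it had 186 (105 higher, 81 lower), and without either w1118 array 70. Without the line 89 array with 2 copies or 1 copy it had 1138 or 985.

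Outside the fly genes, 2 Affymetrix control probe sets that the annotation does not name were bright in the GAL4 arrays and dark in w1118. The first averaged 1870 ± 471 (SD, n = 3) in X1, at least 114-fold above w1118, where it lay at 14.4 and 14.1. In line 89 it lay at 2367 with 2 copies and 417 with 1 copy, a ratio of 5.68. The other averaged 527 ± 65.0 (SD, n = 3) in X1, at least 32.8-fold above w1118, and lay at 1495 and 1010 in line 89. One more unnamed control probe set ran the other way, at 129 and 91.5 in w1118, and 4.9 to 10.7 in the 5 GAL4 arrays.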

How the results depend on the processing

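Scaling to the hybridization controls and the filter at a brighter group mean of 100 were chosen after the data had been seen. The count of calls of X1 against w1118, 3404 in the main fit, stayed within 1.5 times under several settings. It was 3412 with quantile normalization, 3824 with a shift to one median and 2412 with a floor of 1. The probe sets under the median left out gave 3222, an intensity trend 3226, 7 arrays in the fit 2857 and a 2-fold minimum 2431. Hybridization scaling gave 2576 (1964 higher and 612 lower) and the filter at 100 gave 2920. The probe sets called changed more than the count. Of the 3404, 2825 stayed called with quantile normalization, 2070 with a floor of 1 and 1865 with hybridization scaling. With the probe sets under the median left out 2194 stayed called, and with the filter at 100 2015. Falls outnumbered rises (1997 and 1407) except with a floor of 1 or 64, hybridization scaling, the filter at 100, one GAL4 group or adjusted p under 0.01. The count was 1394 with a floor of 64, 1822 with no moderation of the variance, 1230 with all 5 GAL4 arrays as one group and 1181 at adjusted p under 0.01. Leaving out arrays gave 1619 (without X1 replicate 2) to 4170 (without X1 replicate 1), with 1663 without X1 replicate 3. Where this left 1 array in a group, it was assumed to vary like the others. Line 89 against w1118 had 409 calls with a floor of 1, 489 with a floor of 64, 438 with no moderation of the variance and 1535 with hybridization scaling. Leaving out arrays gave 254 (without X1 replicate 3) to 1804 (without the array with 1 copy), with 478 (178 higher, 300 lower) and 510 (193 higher, 317 lower) without w1118 replicates 1 and 2 and 289 without X1 replicate 2. X1 against line 89 had 62 calls with a floor of 1, 113 with a floor of 64 and 67 with no moderation. Leaving out arrays gave 0 (without X1 replicate 2 or 3) to 1138, with 186 without X1 replicate 1, 70 without either w1118 array and 985 without the array with 1 copy.

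With a replicate block each of the 3 contrasts had 0 calls in limma, at 1 or 2 residual degrees of freedom, with 4491, 2317 and 2455 probe sets at an unadjusted p under 0.05. The smallest adjusted p was 0.150, 0.106 and 0.318, and 100% of the original calls had the original sign. Arrays of equal number in X1 and w1118 were not alike (r = -0.049 and -0.012 across probe sets after removing group means), so the numbers do not appear to pair them. The share of X1 calls with the X1 sign in both line 89 arrays, 74.3%, was 77.7% after quantile normalization, 76.7% after a shift to one median, 81.7% and 80.1% with floors of 1 and 64, 79.4% with no moderation and 83.2% with hybridization scaling. It ranged from 69.4% to 78.9% with an array left out, and a replicate block gave no calls and so no share. The copy number median of the rises was 0.512 and 0.479 with floors of 1 and 64, 0.124 with hybridization scaling, and 0.338 to 0.508 with an array left out. That of the falls was -0.293 after quantile normalization, -0.385 and -0.234 with floors of 1 and 64, -0.365 without the probe sets under the median, -0.538 with hybridization scaling, and -0.296 to 0 with an array left out, the latter without either w1118 array. Neither could be computed without a line 89 array.

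Camera called 3 lists after quantile normalization (autophagy, cytosolic ribosomal proteins and proteasome), 1 with a floor of 64 (heat shock and chaperones) and 1 with hybridization scaling (detoxification), while fry called 9. These camera calls used the preset correlation of 0.01, whereas the main fit estimated 0.515 for autophagy, 0.206 for ribosomal proteins, 0.132 for proteasome and 0.180 for heat shock, and called 0 with the estimates (adjusted p of at least 0.873). Leaving out arrays gave 0 or 1, the latter without w1118 replicate 2 (heat shock and chaperones). Of 124 named values, calls ended for 11 after quantile normalization, 8 after a shift to one median, 34 and 39 with floors of 1 and 64, 38 with no moderation and 28 with hybridization scaling. All 5 GAL4 arrays as one group ended 66 of 104, a replicate block 124 of 124, and a left-out X1 or w1118 array 16 to 54. Among the named genes RpL24-like (-0.02), Rpn1 (-0.10) and ND-MLRQ (-0.08) turned after quantile normalization, and Galt (0.01) and ND-20 (0.18) with hybridization scaling. The cause was not tested for these differences, apart from the stricter threshold, which calls fewer by construction. The GAL4 site test and its windows of other lengths were not run. In the X1 arrays 23.4% to 30.0% of probe sets lay under 16, where the signal over background limits any reading of a fall.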

Other observations

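The tests of the floor, of scaling to the hybridization controls, of the fly control transcripts, of neighbours with gene bodies that do not overlap, of neighbours among genes not called in line 89, and of other splits of the arrays were chosen only after the result was seen. The JAK/STAT genes and the tetraspanin genes named here were chosen after their values were seen. Beside upd1, its relative upd2 rose in X1 from 29.9 to 795 (4.72 ± 0.21, adjusted p = 0.00228), with 200 and 72.4 in line 89 with 2 copies and 1 copy. The gene of their receptor, dome, rose from 405 to 3360 (3.09, adjusted p = 0.0116). Expression of ken, which encodes a transcriptional repressor, rose from 325 to 1750 (2.40), and Ptp61F, for a phosphatase that acts on the pathway, fell from 1010 to 170 (-2.58). Stat92E, for the transcription factor of the pathway, was at 2240 in w1118 and 905 in X1 and was not called (-1.36, adjusted p = 0.0775), nor was chinmo (0.42, adjusted p = 0.190). In line 89 against w1118, upd1 (adjusted p = 0.0304) and ken (0.0489) were called. There dome (adjusted p = 0.053), upd2 (0.123), Ptp61F (0.137), Stat92E (0.524) and chinmo (0.294) were not called. The genes upd3, hop and Socs36E were looked for as well and had no probe set with 1 symbol under these names.

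Many of the genes that rose were neighbours on the chromosome. The 247 genes that fell at least 4-fold had 12 adjacent pairs, 2.32 times the shuffled mean of 5.18 but within the range of 0 to 14. Whether falls group as well is left open. Runs of at least 3 adjacent genes that each rose at least 4-fold numbered 19 and held 64 genes. On arm 2R the tetraspanin genes Tsp42Ef (3.96), Tsp42Eg (2.16), Tsp42Eh (4.01) and Tsp42Ei (2.71) rose together, as did Tina-1 (5.06), CG15861 (7.40) and CG3770 (7.32). On arm 2L a run of 5 genes held CG3625 (5.57), Amnionless (4.88), CG11562 (6.17), U2af38 (2.89) and Stip1 (2.10). On arm 3L it was CG9449, CG9451 (7.42, at least 172-fold) and CG9452 (6.81).

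Of 524 genes that rose at least 4-fold in X1, 99 pairs were adjacent, against 22.8 on average and at most 37 in 1000 shuffles of the calls over 11888 genes. Probe sets shared between genes did not account for this, with 85 pairs (at most 32 in shuffles) among genes without cross-matching probe sets. A background peculiar to X1 is argued against for genes that rose in line 89, with 33 pairs (at most 12). Genes not called there had 24 pairs (at most 15). This subset cannot decide on such a background, because a gene not called may still have risen in line 89. Only 822 probe sets were called there, against 3404 in X1. For these genes such a background stays open. Overlap of annotated genes was not the whole cause, because 74 pairs did not overlap, against 18.9 on average and at most 32 in shuffles. At gaps of at least 2000 bases 12 pairs remained, within the 0 to 16 of the shuffles (6.87 on average), so the excess lay mostly among close neighbours. This was the test of overlap set beforehand, and its result is the one that overlap as the cause would give. It also leaves out close neighbours that do not overlap, so it cannot separate overlap from closeness. Neighbours were taken among the 11888 genes, so genes not measured may lie between them. Transcription running on from one gene into the next, regulatory sequence shared by close neighbours and the general grouping of active genes may each contribute and were not tested. A background that both GAL4 lines share and w1118 lacks, and the response to GAL4 itself, stay open too. The design cannot tell them apart, and the site test was not run.

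Among dim probe sets, with a brighter group mean under 64, 812 fell and 145 rose in X1. A lower signal of the X1 arrays would be excluded by the bound set beforehand, 1.5 falls per rise after quantile normalization, which gave 513 falls and 237 rises, a ratio of 2.16. It stays open all the same, because that bound took all arrays to have 1 distribution. Scaling to the hybridization controls, which were lower in X1 by 0.61 ± 0.50 (SD over 9 probe sets, log2 scale), gave 195 falls and 314 rises. These controls did not drop alike: the dimmer bioB probe sets changed by -1.55 to -0.76, the brighter bioD and cre ones by -0.32 to 0.02. A single offset per array is thus a rough scaling. In line 89 the same controls changed by -1.57 to -0.06, and its calls, not split by brightness here, were 513 higher and 309 lower. The floor of 16 as the whole cause is argued against by the 393 falls and 173 rises, a ratio of 2.27, with a floor of 1. It may account for part, since 35.5% of the 812 falls (288) stayed called with that floor and 367 had every X1 array under 16, where the floor of 16 sets the spread to 0, but whether the rest reflects the response to GAL4 was not tested.

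The bacterial poly-A control transcripts lost 5' signal against 3' signal in X1, by -2.1 on average on the log2 scale against w1118 (SD 0.88 over 4 transcripts, from -2.95 for dap to -0.87 for thr). In the 3 fly control transcripts the same ratio changed by -0.27 ± 0.09 (SD), which argues against labelled fly RNA in X1 being shorter to a like extent. The X1 arrays also stood apart from line 89 in the bacterial ratios. With 2 copies and 1 copy of line 89 these were -1.89 and -1.85 for dap, against -4.26 in X1, and -1.52 and -1.25 for lys, against -2.98. For phe they were -0.87 and -1.33, against -2.99, and for thr -1.75 and -1.57, against -2.21. The state of the added control RNA could differ between labelling batches, but the labels give no batch, and no biological explanation was tested.

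Of the 10 splits of the 5 arrays into 3 and 2, 1 split, the real one, gave as many as 3404 calls, and the highest of the other splits gave 0. The splits are too few for a share under 0.05.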
